A study of Mus musculus with 8 samples.

How the data were processed

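RNA methylation was profiled in gastrocnemius, a calf muscle, of 10-week-old male C57BL/6 mice by m6A MeRIP-seq, in which RNA is captured with an antibody against N6-methyladenosine and sequenced next to the uncaptured input RNA. Per the labels' protocols, RNA was harvested with Trizol, and libraries were made with a strand-preserving low-input total RNA kit. The series holds 8 libraries, an immunoprecipitated (IP) and an input library for each replicate. There are 2 replicates of denervated muscle, taken 14 days after denervation, and 2 of innervated muscle. The innervated muscles were contralateral controls, that is, muscles of the opposite leg. Replicates were taken from the labels, which do not say that the numbers mark separate animals. P-values computed over libraries and spreads between replicates thus measure the spread between these samples, which may be technical. P-values of Fisher's exact tests are computed over genes and do not measure that spread.

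The deposited values were 4 peak lists, 1 per IP library, each called against the input library of the same group and number and not pooled. Each list gives the position, strand, blocks and gene name of a peak on mm10. The column of peak values is called score per the file headers. It is the authors' own value and ran from 0 to at most 0.023. What the score measures, the peak caller and its limit are not given in the sources used here; the submitters' processing notes name STAR 2.4.2a, ChIPseeker and mm10. Small scores were read as strong peaks, because the range is that of a p-value. Peaks of the list's smaller-score side recurred in another list more often in 3 of the 4 lists (93.8% against 91.0%, 88.7% against 85.6%, and 92.5% against 86.7%), but not in the list of denervated replicate 2 (87.1% against 87.9%), so this reading is uncertain. The planned wording "highest score" was applied as strongest, that is, smallest score. Scores were used only to rank or filter peaks within a list, as a percentile that is 100 at the smallest score.

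Read counts were not analysed here. The depth of each library is therefore unknown, transcript levels in the inputs are unknown, and no methylation level per site can be given. A peak call needs enough reads, so it depends on the abundance of the transcript as well as on its methylation. Without depth, the absence of a peak is no evidence that a transcript was unmethylated. Intervals for shares of peaks are Wilson intervals at 95% and cover counting error only.

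Peaks of the 4 lists that shared at least 1 base on the same strand, counting blocks and not the introns between them, were linked into regions. A region or gene was called denervated only if both denervated lists and neither innervated list held it, and innervated only in the opposite case. Because any arrangement of 4 libraries into 2 pairs yields such classes, the same counts were made for the other 2 arrangements, that is, number 1 against number 2, and crossed numbers (innervated 1 and denervated 2 against innervated 2 and denervated 1). Regions were also counted only in genes that held another region called in all 4 libraries. Overlap between lists was measured as the Jaccard index of covered bases and as the mean percent of peaks overlapped. Group means were compared by two-sided exact permutation tests over 2 against 2 libraries, whose smallest possible p is 0.333. Gene names were taken from the lists and matched to RefSeq symbols of GRCm38.p6, the assembly of mm10: of 5987 names, 5725 were symbols, 249 were older symbols and 13 were not matched. Gene names shared by 36 regions were kept side by side. Place along a gene was taken from the gene's span in that table, because exon and UTR annotation and the genome sequence were not used here. The shares of peaks in UTRs and coding sequence and the share with the m6A motif, both planned, were therefore not run.

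Before the data were examined, 20 gene lists were fixed, 6 of them for cell types other than muscle fibres. Each list with at least 3 genes in the background was tested among denervated-only and innervated-only genes by two-sided Fisher's exact tests, against the genes with a peak in at least 2 libraries, with Benjamini-Hochberg adjustment over all 36 tests and a threshold of 0.05. Genes are not independent replicates. The comparison of lists by their share of genes called in all 4 libraries, also by Fisher's exact test over the 20 lists, was added after the data were seen. Named genes followed a rule fixed beforehand: Hdac4, Foxo3, Alkbh5, Fto, Mettl3 and Mettl14 always; for each direction the 10 protein-coding genes with the highest mean percentile of their best peak; and for each list the first 4 members, in list order, that were group-specific. Some genes that the rule selected are not reported here. Genes named outside the rule, including list members given as examples of calls in all 4 libraries or of no peak, were chosen after their values were seen.

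Settings chosen beforehand for comparison were the 50% of each list with the smallest scores, equal numbers of peaks per list, reciprocal overlap of at least 50%, absence within 500 bases, assignment by gene body, a background of genes called in at least 1 library, a common score limit, pairing by replicate number, and leaving out each library. The 50% of each list with the largest scores, the joining of peaks at most 200 bases apart, and removal of genes that share a region with another gene were added after the data were seen. A gene whose peaks all lay in the same 50% of the lists by score lost its call in the other 50% by construction. The scripts were tested on simulated lists built from 13080 regions of 5949 genes with library membership shuffled. For the denervated against innervated comparison, 100% of 200 planted denervated-only regions were recovered, a planted list of 20 genes with 10 planted members passed its test, and 0 lists passed in 20 draws without planted regions. Planted regions met the class definition exactly, so their recovery checks the code only. The draws shuffled each region on its own and did not keep the list lengths or the linkage of regions in a gene. They therefore say little about false positives in the real lists. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.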

Results

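Peak lists of m6A-bearing RNA were compared between mouse gastrocnemius muscles denervated for 14 days and innervated muscles of the opposite leg, with 2 IP libraries per group. The lists held 9327 and 10300 peaks in innervated replicates 1 and 2, and 9804 and 9496 peaks in denervated replicates 1 and 2. The means were 9814 ± 688 (SD, n = 2) and 9650 ± 218 (SD, n = 2), and the difference did not exceed the spread between replicates (exact permutation p = 1). Peaks lay in 4149, 4642, 4601 and 4230 genes in the same order, and their median length was 249 to 250 bases. Together the 4 lists made 13116 regions in 5981 genes. Of these, 4541 regions (34.6%) and 2921 genes (48.8%) were called in all 4 libraries, and 4232 regions were called in 1 library only.

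Transcripts of chromatin regulators were called in every library more often than the genes of the other lists pooled. Of 71 transcription and chromatin regulators, 33 had a peak in all 4 libraries, among them the histone methyltransferases Kmt2a, Kmt2c and Kmt2d, the acetyltransferases Ep300 and Crebbp, and the methylcytosine dioxygenases Tet2 and Tet3. That was 46.5%, against 25.5% of the pooled genes of the other lists (odds ratio 2.54, Fisher's exact test, adjusted p = 0.00783 over 20 lists). No other list passed that test, although m6A writers, with 5 of 11 genes, and myogenic transcription factors, with 11 of 26, had similar shares. Members of these lists named here as called in all 4 libraries are examples chosen after their values were seen. Growth and anabolic signalling had 28 of 68 genes called in all 4 libraries, including the receptors Igf1r and Insr (Fisher's exact test, adjusted p = 0.0676). Endothelial and perivascular genes had 15 of 37, including Cdh5 and Kdr, and extracellular matrix genes had 25 of 68, including Col6a1 and Vcan. Sarcomere and cytoskeleton genes had 10 of 65, including Speg, Xirp1 and Plec, and mitochondrial genes had 9 of 62, including Ppargc1a, the coactivator of mitochondrial biogenesis. Both shares were lower than those of the other lists pooled (odds ratios 0.452 and 0.422, adjusted p = 0.0676 in Fisher's exact test). Lower shares with the same adjusted p were found for Schwann cell genes (4 of 40, odds ratio 0.279). The neuromuscular junction and denervation response list had them too (6 of 47, odds ratio 0.367). Which of these genes were expressed was not measured here, and transcript length was not taken into account. A gene counted as called if it held any peak, and Kmt2c, Kmt2a and Kmt2d held 8, 7 and 7 regions called in all 4 libraries. Fat4, an atypical cadherin, carried 14 regions called in all 4 libraries, and Ahnak, a giant scaffold protein, carried 13; both were singled out after their values were seen.

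The atrophy regulators Hdac4 and Foxo3, a histone deacetylase and a forkhead transcription factor, were called in all 4 libraries. Each gene had a single region. That of Hdac4 lay on chromosome 1 from 91932799 to 91933667, on the minus strand near the 3′ end of the gene span, and that of Foxo3 on chromosome 10 from 42185985 to 42197002, also on the minus strand. Of the HDAC4 and FoxO list, 8 of 20 genes were called in all 4 libraries, Foxo1, Foxo4 and Foxo6 among them, and 0 were group-specific. Transcripts of the m6A methyltransferase subunits Mettl3 and Mettl14 and of the demethylases Alkbh5 and Fto carried no peak in any list. The writer-complex genes Wtap, Zc3h13, Rbm15, Rbm15b and Cbll1 and the reader genes Ythdf1, Ythdf2 and Ythdf3 were called in all 4 libraries. Mettl16, a separate m6A methyltransferase, was called in the innervated libraries alone, on chromosome 11 from 74817358 to 74817655, a call lost with the 50% of each list with the smallest scores.

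**Figure D1:**
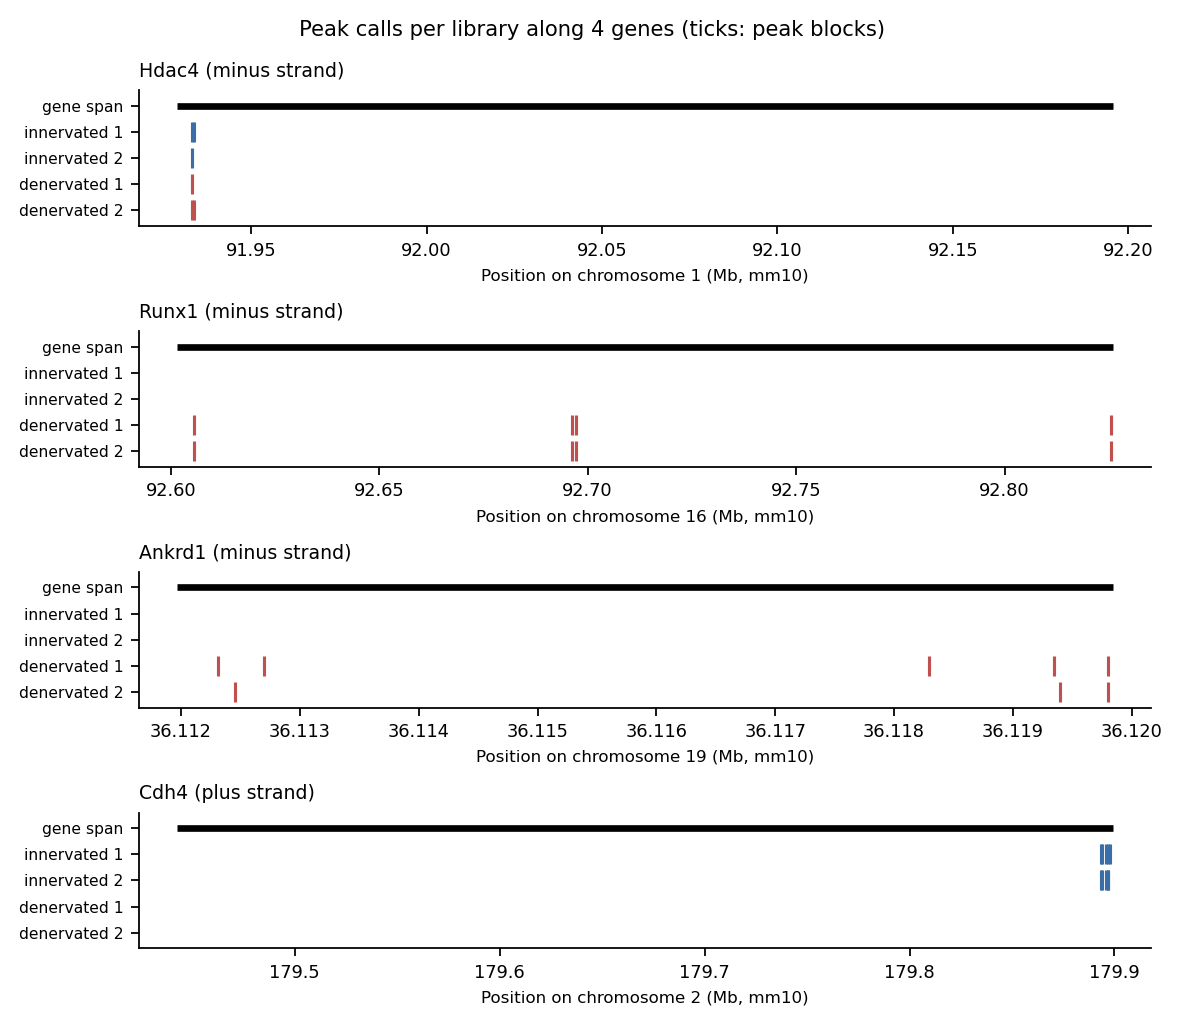
Peak blocks (vertical ticks) in each of the 4 IP libraries along the gene spans (black bars) of Hdac4, Runx1, Ankrd1 and Cdh4; the horizontal axis is the position on the chromosome in megabases of mm10, with innervated libraries in blue and denervated libraries in red. Hdac4 was called in all 4 libraries, Runx1 and Ankrd1 in both denervated libraries alone, and Cdh4 in both innervated libraries alone.

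The main comparison asked which transcripts carried m6A peaks in denervated but not in innervated muscle, and the reverse. Genes of the neuromuscular junction and the denervation response were over-represented among denervated-only genes. Of the 17 members of that list with a peak in at least 2 libraries, 6 were denervated only, including Chrnd, the delta subunit of the muscle acetylcholine receptor, Runx1, a transcription factor induced in denervated muscle, Ankrd1, an ankyrin-repeat protein of stressed muscle, Kcnn3, a calcium-activated potassium channel, and Nrcam, a neural adhesion molecule. That was 35.3%, against 4.13% of the other genes (odds ratio 12.7, Fisher's exact test, p = 4.52e-05, adjusted p = 0.00163 over 36 tests). It was the only one of the 36 tests to pass, and a second had an unadjusted p under 0.05; the other arrangements of the libraries gave 0 lists past the threshold, with smallest exact p values of 0.0620 and 0.148. Gadd45a, a stress-response gene, and Cdh4, a neural cadherin, were innervated only (2 of 17, odds ratio 3.30, Fisher's exact test, adjusted p = 0.723). The denervated and innervated sides were not tested against each other. Genes called in all 4 libraries cannot be group-specific. They were 2921 of the 4810 background genes but 6 of the 17 list members, which may raise the list's odds ratio on either side. The junction genes Musk, Lrp4 and Colq were called in all 4 libraries. Markers of other cell types, pooled over 6 lists, gave 6 denervated-only genes of 85 (odds ratio 1.74, Fisher's exact p = 0.175) and 0 innervated-only genes of 85. The list's call was lost with the 50% of each list with the smallest scores (4 of 10 members, Fisher's exact test, adjusted p = 0.162), with the 50% with the largest scores (4 of 10, adjusted p = 0.209 by the same exact test), and without denervated replicate 1 (odds ratio 6.18, adjusted p = 0.0598, exact test). Of the list members named above, Chrnd, Runx1, Ankrd1, Gadd45a and Cdh4 were no longer group-specific with the smallest scores, and Nrcam and Gadd45a with the largest. The list passed without innervated replicate 1 (odds ratio 7.87, adjusted p = 0.0230), innervated replicate 2 (odds ratio 6.50, adjusted p = 0.0333) and denervated replicate 2 (odds ratio 6.61, adjusted p = 0.00971), all by Fisher's exact test. Leaving out a library loosens the definition, so the 204 denervated-only genes all stayed in by construction. These passes are therefore not independent of the main test.

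Chrnd held its denervated-only region on chromosome 1 from 87198835 to 87199181. Runx1 held 3 such regions on chromosome 16, from 92605454 to 92605802, from 92695792 to 92696838, and across introns from 92697088 to 92825596. Ankrd1 held 2 on chromosome 19, from 36112112 to 36112798 and from 36119292 to 36119844. Gadd45a held its innervated-only region on chromosome 6 from 67035438 to 67036686. Ankrd1, Kcnn3, Nrcam and Cdh4 lay outside the naming rule and were chosen after their values were seen.

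**Figure D2:**
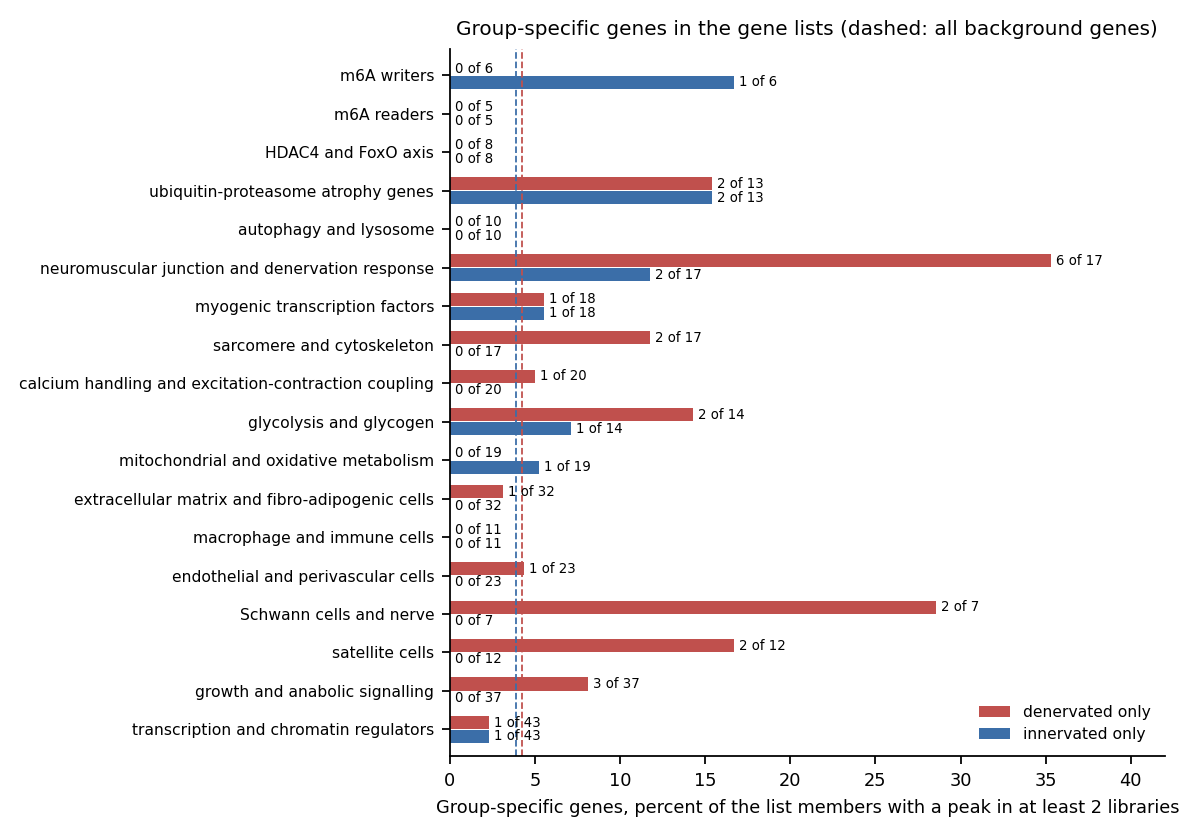
Percent of the members of each gene list with a peak in at least 2 libraries (horizontal axis) that were denervated only (red) or innervated only (blue), with the numbers of genes beside the bars and the percent among all background genes as dashed lines. The denervation-response list stands at 6 of 17 denervated-only genes; the Schwann cell list has 2 of 7.

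Other gene groups contributed single members that did not amount to a list past the threshold. Among ubiquitin-proteasome atrophy genes, the ligase genes Fbxo32 (atrogin-1), Fbxo30 and Traf6 were called in all 4 libraries, Fbxo31 and Klhl41 were denervated only, Cblb and Zfand5 were innervated only, and Trim63 had no peak. Myod1, the myogenic determination factor, was denervated only, on chromosome 7 from 46376572 to 46376767, and Srf, a regulator of actin and muscle genes, was innervated only, with 3 regions on chromosome 17. Of growth signalling genes, the ligands Gdf5 and Gdf15 and the receptor Bmpr2 were denervated only and 0 were innervated only (3 of 37, Fisher's exact test, adjusted p = 0.766). Gdf5 held 2 denervated-only regions on chromosome 2, from 155941123 to 155942207 and from 155944625 to 155945167. The sarcomere genes Mylk4 and Myom1, the calcium-binding Hrc and the glycolysis and glycogen genes Gpi1 and Phka1 were denervated only. Ppp1r3d, which targets a phosphatase to glycogen, and Slc25a25, a mitochondrial carrier, were innervated only. Of chromatin regulators, Kdm3a was denervated only and Ncor1, a corepressor, innervated only. Among markers of other cells, the Schwann cell genes Ngfr and Sox2 (2 of 7, Fisher's exact test, p = 0.0327, adjusted p = 0.588), the satellite cell gene Peg3, the endothelial Mecom and the matrix gene Fbn1 were denervated only. Myod1 is also on the satellite cell list, which thus had 2 of 12 (odds ratio 4.55, Fisher's exact test, adjusted p = 0.700). Several of these calls ended in other settings. Fbxo31, Gdf15 and Kdm3a lost theirs with equal numbers of peaks per list, and Peg3 and Mylk4 with assignment by gene body. With the 50% of each list with the smallest scores, these 5 genes and Cblb, Myod1, Gpi1, Slc25a25, Mecom, Ngfr, Gdf5 and Ncor1 lost theirs. With the 50% with the largest scores, Zfand5, Klhl41, Gdf15, Bmpr2, Myom1, Hrc, Phka1, Ppp1r3d, Ngfr, Sox2 and Fbn1 did. A gene whose peaks all stood on the same side of the 50% limit lost its call on the other side by construction. Srf kept its call in each of these settings, with regions on both sides of the limit (mean percentiles 65.45, 34.22 and 34.22). Of the members of the fixed macrophage and immune list and of the fixed autophagy list, 0 were group-specific. Immune genes outside that list, such as Cd180, were denervated only, as given below. The single member of the erythroid list with a peak, Epb41, was called in all 4 libraries.

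Across all genes, 204 were denervated only and 188 innervated only, 192 and 177 of them protein coding. The denervated-only genes with the smallest scores, and so the highest mean percentile within their lists, included Cd180, a receptor of B cells and macrophages (97.3), Trim44, of the tripartite motif family (96.8), Prr15 (96.3), Galnt4, a glycosyltransferase (94.6), and Cd101, an immunoglobulin-family surface protein (91.4). Mycl, a Myc-family factor, Gpr65, a proton-sensing receptor, Chst14, a dermatan sulfotransferase, Ndufaf4, an assembly factor of respiratory complex I, and Ncald, a neuronal calcium sensor, completed the 10, at 84.8 to 89.1. On the innervated side were, among others, Zfp108, a zinc finger protein (99.3), Grin3b, an NMDA receptor subunit (98.3; its call was lost with assignment by gene body), Igfals, a carrier subunit of insulin-like growth factors (92.7), and Zfp101 (91.0). Tll1, Spin4, Med11, Ppp1r3d and Apex2 followed at 88.4 to 90.8. Igfals held 2 innervated-only regions on chromosome 17, from 24880536 to 24880634 and from 24881321 to 24881812. Cd180 held 3 denervated-only regions on chromosome 13, from 102705147 to 102705246, from 102706087 to 102706334 and from 102706532 to 102706631. This order turns if large scores mark strong peaks, a reading that was not excluded. All genes named in this paragraph, which were chosen for small scores, lost their calls with the 50% of each list with the largest scores. With the 50% of each list with the smallest scores, 201 and 211 genes were group-specific, of which 56 and 59 were among the 204 and 188. With the 50% with the largest scores these were 233 and 232 genes, of which 89 and 77 were among them.

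The 392 group-specific genes compare with 241 when the libraries were arranged as number 1 against number 2 and 267 with crossed numbers. The 1032 group-specific regions (481 denervated only and 551 innervated only) compare with 630 and 642. The actual grouping thus gave 1.54 times as many genes and 1.62 times as many regions as the mean of the other arrangements. In a single direction the excess did not always hold: crossed numbers gave 208 genes on the side of innervated 2 and denervated 1, and 59 on the other. Leaving out a library loosens the definition. Denervated-only genes then numbered 352, 514, 460 and 574 without innervated 1, innervated 2, denervated 1 and denervated 2, and innervated-only genes 547, 374, 512 and 395. Denervated-only regions numbered 814, 1124, 1739 and 1596 in that order, and innervated-only regions 1939, 1368, 1209 and 1075.

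**Figure D3:**
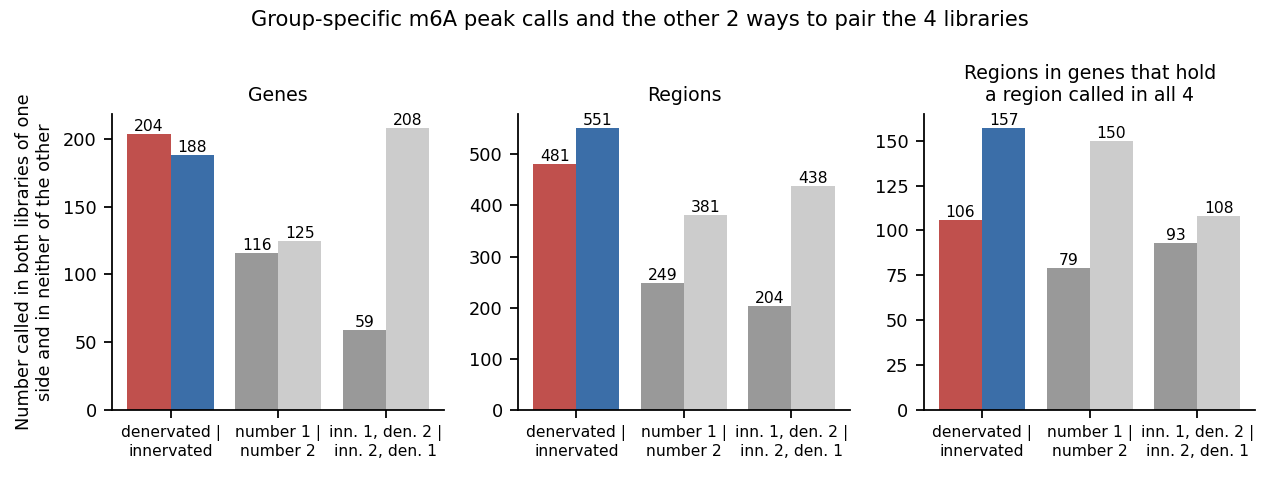
Numbers of genes, regions, and regions in genes that hold another region called in all 4 libraries (vertical axes) that were called in both libraries of one side and in neither of the other, for the 3 ways to arrange the 4 libraries; the left bar of each pair counts the side named first. The actual grouping (red denervated only, blue innervated only) gave 204 and 188 genes; of the others (grey), crossed numbers gave 59 and 208.

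Libraries of a group shared more of the covered bases than libraries of different groups. The Jaccard index was 0.579 between the innervated lists and 0.559 between the denervated lists, and 0.528 to 0.551 between groups. The mean within groups exceeded that between groups by 0.0286, whereas the other arrangements gave −0.0126 and −0.0160. With the remaining pair set against its overlap with the third library, the difference was 0.0134 without innervated 1, 0.0231 without innervated 2, 0.0458 without denervated 1 and 0.0320 without denervated 2. With 3 arrangements, the smallest share the actual grouping can reach is 0.333. By the percent of peaks overlapped the groups were less distinct: innervated 2 and denervated 1 shared 73.8%, and both denervated lists 73.6%.

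Transcripts that were detectable in every library also held group-specific regions. Among those with the smallest scores in their lists were a denervated-only region of Purb, a purine-rich element binding protein, on chromosome 11 from 6475278 to 6475527, and regions of Naa30, an acetyltransferase subunit, and Nfil3, a leucine zipper factor. On the innervated side were a region of Mfsd5, a membrane transporter, on chromosome 15 from 102280451 to 102280799, and regions of Synpo, an actin-associated protein, and Ankrd50. These genes were chosen after their values were seen. Peaks of the same gene often had equal scores, so the rank may belong to the gene and not to the single region. The Synpo regions, for example, stood at the same mean percentile of 97.85. In all, 106 regions in such transcripts were denervated only and 157 innervated only. Their total of 263 compares with 229 and 201 in the other arrangements, a ratio of 1.22 to their mean. Of the settings with all 4 libraries, the total fell below another arrangement only with the 50% of each list with the smallest scores (59 against 63). It was 95 against at most 75 with the 50% with the largest scores, 551 against 478 with reciprocal overlap and 165 against 124 with joined peaks. Group-specific regions beside a region called in all 4 libraries were not excluded from these counts. The planned absence within 500 bases was applied only to group-specific regions of all genes together, and its counts are not reported here. In Cep350, an example chosen after its values were seen, an innervated-only region on chromosome 1 ended at 155846908. A region called in all 4 libraries started at 155846957. Without innervated 1, innervated 2, denervated 1 and denervated 2, the denervated-only regions numbered 275, 346, 661 and 441, and the innervated-only regions 657, 466, 422 and 446. Reciprocal overlap of at least 50% gave 242 and 309, and joining neighbouring peaks, an alternative chosen after seeing the data, gave 61 and 104.

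Peaks lay mostly near the 3′ end of the gene span in both groups. The span includes introns, and the share of exon sequence along it was not measured, so no preference within transcripts is shown. The last 20% of the gene span held 55.7% of peaks in innervated replicate 1 (95% Wilson interval 54.7 to 56.7), 57.2% in innervated replicate 2 (56.3 to 58.2), 56.5% in denervated replicate 1 (55.5 to 57.5) and 54.3% in denervated replicate 2 (53.3 to 55.3). The group means, 56.5 ± 1.08 and 55.4 ± 1.55 (SD, n = 2 each), did not differ beyond the spread between replicates (exact permutation p = 0.667). Peaks in regions called in all 4 libraries had median lengths of 300 to 350 bases, against 199 to 200 for denervated-only and 151 to 199 for innervated-only regions. Their median percentile within the lists, which is high for small scores and turns if large scores mark strong peaks, was 52.3 to 57.1, against 42.4 to 43.3 and 42.9 to 44.9. Peaks called in 1 library only ranged from 31.7 to 52.5, and in denervated replicate 2 they stood at 52.5, level with the 52.3 of its peaks in regions called in all 4 libraries.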

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

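The 50% of each list with the largest scores, joined neighbouring peaks, the 50% variant of peak position and removal of genes that share a region were chosen after seeing the data; the other settings were planned. The excess of group-specific genes over the other arrangements and the higher overlap within groups held in every setting in which they were computed. With the 50% of smallest scores, regions in genes with a region called in all libraries fell to 29 and 30, and their ratio to the other arrangements to 1.01; 0 lists passed, and the denervation list had an odds ratio of 8.23 among denervated-only genes. With the 50% of largest scores these were 48 and 47, a ratio of 1.30, 0 lists and 7.60. Fewer genes can be tested in shortened lists, and other causes were not tested. Reciprocal overlap gave 242 and 309 such regions and joining gave 61 and 104, as splitting or merging regions does by construction. Of the 47 group-specific genes named by rule, 44 kept their calls with assignment by gene body. Of the 27 named by list order, 24 kept them with equal numbers of peaks and 10 with the 50% of smallest scores; the other 20 were chosen for small scores. Which side had more calls was not stable: 204 and 188 genes (denervated and innervated only) became 201 and 211 with the 50% of smallest scores, and 106 and 157 regions in genes with a region called in all libraries became 48 and 47 with the 50% of largest scores.

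Leaving out each library, which loosens the classes by construction, gave 814 to 1739 denervated-only and 1075 to 1939 innervated-only regions, 275 to 661 and 422 to 657 in genes with a region called in all libraries, and 352 to 574 and 374 to 547 genes. Lists past the threshold numbered 0 to 1, and the odds ratio of the denervation list was 6.18 to 7.87; it missed the threshold without denervated replicate 1. The Jaccard index within groups exceeded that between groups by 0.0134 to 0.0458, and the percent of peaks overlapped by 0.561 to 4.27.

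The replicate numbers were not taken as pairs, because the labels do not say that they mark animals. Across 5981 genes, the deviations of same-numbered libraries had a correlation of 0.00295. With 2 libraries per group, this cannot show whether same-numbered libraries came from the same animal. With a replicate block the difference in peaks per library was −163.5 (exact sign-flip p = 1, smallest possible 0.5), and the 204 and 188 genes were the same by construction. The planned shares of UTR and coding peaks and of peaks with the motif were not run, nor were their alternatives. Depth is unknown, so it could not be set beside any count.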

Other observations

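The genes singled out here, the scan of gene families and the tests of explanations were chosen after the values were seen. The denervated-only genes below are single examples of the 204, and no group they belong to was tested for enrichment except where said. The sodium channel genes Scn2a and Scn3a and the muscarinic receptor gene Chrm3 were called in both denervated libraries and in neither innervated library. Scn2a held a denervated-only region on chromosome 2 from 65764601 to 65765200, and Chrm3 on chromosome 13 from 9878246 to 9878691. Mymx, which encodes the myoblast fusion peptide myomixer, was denervated only, with 2 regions on chromosome 17 from 45601064 to 45601211 and from 45601260 to 45601552. Ccr7, a chemokine receptor, Ciita, the transactivator of MHC class II, and Nod2, a sensor of bacterial cell walls, were denervated only, whereas 0 of the 11 tested genes on the fixed macrophage and immune list were. These calls depended on the score limit, in part by construction, because a gene with all its peaks on the same side of the limit loses its call on the other. Scn2a, Chrm3, Ccr7 and Ciita lost theirs with the 50% of each list with the smallest scores, and Scn3a, Chrm3, Mymx, Ccr7, Ciita and Nod2 with the 50% with the largest. Ciita also lost its call with assignment by gene body. Amd1 and Amd2, near-identical genes of polyamine synthesis, share a denervated-only region and cannot be separated; Amd1 lost its call with the largest scores, and Amd2 with the smallest and by gene body.

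Single genes stood on the other side as well. Fos and Arc, genes induced by activity, were innervated only, Fos with 3 regions on chromosome 12 between 85475104 and 85476672. So were Nos1 and Aqp4, whose proteins are held at the muscle membrane, the neurotrophin gene Ntf5, and the endothelial genes Cav1, Apold1, Btnl9, Pcdh12 and Adgrf5, although 0 of the 23 tested markers on the fixed endothelial list were innervated only and 1, Mecom, was denervated only. Fos, Arc, Aqp4, Cav1, Apold1, Btnl9 and Adgrf5 lost their calls with the 50% of each list with the smallest scores, and Arc, Nos1, Aqp4, Ntf5, Apold1, Btnl9 and Pcdh12 with the 50% with the largest. Cav1 also lost its call with equal numbers of peaks per list. A scan of 38 gene families defined by name stems (76 tests) gave 0 families past the threshold and 2 with an unadjusted p under 0.05. These were Zfp genes, with 1 of 198 denervated only (odds ratio 0.110, Fisher's exact p = 0.00323, adjusted p = 0.246), and Sox genes, with Sox2, Sox9 and Sox11 as 3 of 11 (odds ratio 8.58, Fisher's exact p = 0.00964, adjusted p = 0.366). Sox9 lost its call with the smallest scores, and Sox2 and Sox11 with the largest.

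The actual grouping gave 392 group-specific genes and the other arrangements at most 267; with 3 arrangements no share under 0.05 can be reached. Unequal list lengths are argued against as the whole cause, because lists of equal length gave 414 genes, against at most 264 in another arrangement. A change in transcript abundance or detection stays open. In genes that held a region called in all libraries the actual grouping exceeded the others 1.22-fold, against 1.83-fold in other genes, so the excess was smaller where the transcript was detectable throughout, but weaker regions of such transcripts also depend on abundance. Without transcript levels, abundance and methylation cannot be told apart, and an effect of denervation on methylation itself may be present but was not separately tested.

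For the denervation-response list among denervated-only genes, the same question of transcript abundance or detection stays open. List members with a region called in all libraries had 4 further regions, of which 0 were denervated only, and so few regions decide nothing. Cells other than muscle fibres could also contribute: their pooled markers had an odds ratio of 1.74 among denervated-only genes (6 of 85, Fisher's exact p = 0.175), which neither reaches the threshold nor lies below 1. Of the 224 pooled genes, 5 are also on other lists. Changed methylation, changed abundance and changed cell makeup after denervation therefore cannot be told apart for these 6 genes.

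Neighbouring peaks of a gene within 200 bases had equal scores in 98.1% to 99.1% of cases. A candidate explanation is that 1 score was given to several peaks of a gene. Neighbours farther apart also had equal scores in 54.1% to 71.0% of cases, against at most 0.380% of random pairs from different genes, as that explanation predicts. Numbers of peaks may therefore exceed the number of separate enriched stretches, and joining such neighbours left 7172, 7893, 7668 and 7190 peaks. No biological explanation was tested.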
